A study of Begonia x semperflorens-cultorum with 3 samples.

How the data were processed

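RNA sequencing of begonia leaves gave 1 library for each of 3 growth conditions, and the condition of each library was taken from its labels. Per the labels' protocols, poly-A mRNA was purified from total RNA with oligo-dT beads, and the libraries were made with the NEBNext Ultra kit for Illumina sequencing. Per the series' design text, 4 parallel samples of a treatment were mixed before RNA extraction.

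Each deposited file lists, per assembled gene, an expected count, a TPM value, an FPKM value, a length, an effective length and the isoforms of the gene. The deposited expected counts are estimates, not whole reads: per the files' values, 11.5% of the genes in LT, 7.58% in HL and 8.60% in CK have a fractional value. TPM (a length-corrected level scaled to the same total in each library) was computed by the authors, per the file headers, and was used here only for levels and for the check of gene numbers. FPKM (a level corrected for effective length and library total) was also computed by the authors, per the file headers, and was used as an alternative scaling with 0.1 added to each value. The assembler, the aligner, the quantification tool and their versions are not given in the sources used here. No genome, sequence or gene annotation was used.

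The length of a gene exceeded its effective length by 100 bases in LT, 87.3 in CK and 84.7 in HL (median over genes longer than 2000 bases). This offset, which lowers the effective length of short genes the most, was thus greater in LT than in CK. Because genes with several isoforms carry an abundance-weighted length, the LT and CK lengths of such genes can differ.

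Expected counts were rounded to whole numbers. The gene sets of the files were compared by gene number, isoform list and single-isoform length. LT and CK shared all of these, and HL did not, so only 1 of the 3 comparisons that the design implies was made. The plan had set the scaling factors on all 3 libraries; they were computed on LT and CK alone, with the trimmed mean of M-values (TMM) in edgeR 4.0.16 (R 4.3.3). Counts were scaled to the mean effective library size and 1 count was added before the log2 fold was taken. With 1 library per group no test across samples exists, so genes were called by a fixed rule of size: at least 50 counts in the higher library and a normalised fold of at least 2. For single genes an exact conditional binomial 95% interval of the fold was computed, and for shares of counts an exact Clopper-Pearson interval. Both cover counting error only. Reads were not collapsed by molecular identifiers, so copies of 1 molecule may be counted apart and the intervals may be too narrow.

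The rule for the genes named in the text was set before the data were examined, as were the rule of size and the alternatives, except where said otherwise. Since no gene names were given, it takes the 2 genes with the largest fold in each direction among those with at least 100 counts in the higher and at least 10 in the lower library. The lists of pigment, cold, light, photosynthesis, hormone and tissue marker genes that had also been fixed could not be applied, because gene numbers could not be matched to names.

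The calling step was tested on simulated data for LT against CK, with counts drawn for the 74779 real genes at their mean levels and 200 genes changed. The changed genes were drawn from those with an expected count of at least 50 in both libraries, so recovery below that level was not tested. With counting noise alone the calling step recovered 100% of the genes changed by 1.5 on the log2 scale. With an assumed biological coefficient of variation of 0.4 between libraries it recovered 73.0% of those, and 99.0% of the genes changed by 3.

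The alternatives were DESeq2 1.42.0 size factors, the total count, the upper quartile, FPKM, TMM without the 100 most abundant genes, other count minimums, added counts and fold limits, the interval limit, thinning to the smallest library, and genes of at least 500 bases. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.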

Results

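Poly-A RNA was sequenced from leaves of the bedding begonia Begonia x semperflorens-cultorum, cultivar Super Olympia, under 3 growth conditions. The low-temperature library (LT) came from plants grown at temperatures of 15 and 5 °C, with light of 300 μmol per square metre and second. The high-light library (HL) came from plants grown at 25 and 15 °C, with light of 500 in the same unit. The control library (CK) had the temperatures of HL and the light of LT, so that each treatment departed from the control in temperature or in light alone. The series is concerned with the synthesis of anthocyanins, the red and purple flavonoid pigments of leaves and petals, under these 2 treatments. Each condition was represented by 1 library made from 4 parallel samples mixed together, so the spread between plants was averaged in the tube and could not be measured. No p-value was therefore computed, and a difference between 2 libraries below is a difference between those libraries.

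The expected counts summed to 18836786 in LT, 17677087 in HL and 17223244 in CK, after rounding per gene. The values belonged to genes numbered in the manner of a transcript assembly, called assembled genes here, and the files paired none of these numbers with a gene name, a sequence or a position in a genome. The genes of the flavonoid pathway, of the cold response and of photosynthesis could for this reason not be picked out, and no pathway list was tested. The LT and CK libraries were quantified on 1 common set of 74779 assembled genes. All 58037 single-isoform genes had the same length in both files.

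The HL library was quantified on another set, of 83699 assembled genes. Of its gene numbers, 68916 also occurred in the CK file, but they did not name the same genes. Among the 47991 shared numbers with 1 isoform in both files, 214 (0.446%) had the same length. Moving the HL values along the numbering, as described below, also did not lower the correlation of HL with CK. The gene-by-gene comparisons of HL with CK and of LT with HL, and the search for genes that differed from CK in both treatments, were not made.

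Counts were spread over more of the abundant genes in the LT library than in the CK library. The 10 most abundant assembled genes held 6.91% of the LT counts (exact 95% binomial interval 6.90 to 6.92%), against 9.27% of the CK counts (9.26 to 9.28%). The same share was 8.49% in HL on its own assembly (8.48 to 8.51%). These intervals cover counting error only. A share of 50% of all counts was reached with the 1276 most abundant genes in LT, with 1029 in HL and with 925 in CK. With at least 10 counts as the minimum, 25461 genes were detected in LT and 25342 in CK on their common assembly, and 26099 in HL on its own. At this minimum the order of LT and CK turned at equal total count: thinned to the CK total, LT had 24917 genes, against 25342 in CK. With at least 50 counts LT had more genes than CK, 17512 against 16665, and 17157 when thinned. With at least 1 count, the numbers were 49268 in LT and 56613 in CK, although LT was the deeper library, and 63470 in HL.

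**Figure D1:**
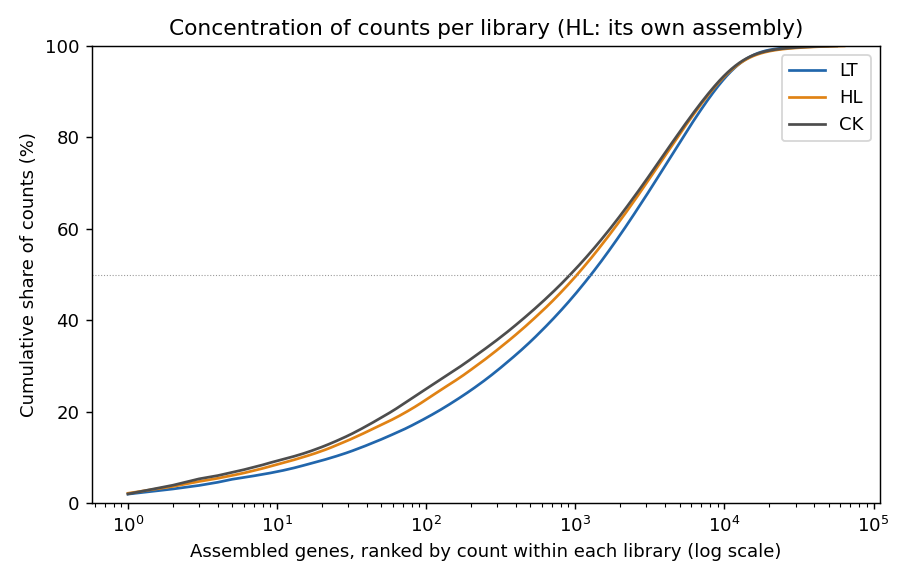
Cumulative share of counts (percent, vertical axis) against the number of assembled genes ranked by count within each library (horizontal axis, log scale), with 1 line per library. The LT line lies below the CK line: its 100 most abundant genes held 18.7% of the counts against 25.0% in CK and 22.7% in HL, which was quantified on another assembly.

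Low temperature was compared with the control to ask which leaf transcripts differed between 2 growth conditions whose labels differ in temperature alone. The libraries also differed in the offset of effective length, 100 bases in LT and 87.3 in CK. With 1 library each, library effects cannot be separated from temperature. Of the 18742 assembled genes with at least 50 counts in the higher library, 3154 (16.8%) were at least 2-fold higher in LT and 2621 (14.0%) were at least 2-fold lower, while 12967 lay within 2-fold. The genes higher in LT held 27.7% of all LT counts and 5.92% of all CK counts. The genes lower in LT held 10.9% of the LT counts and 35.0% of the CK counts. Across the 18742 genes, which are not independent replicates, the normalised counts of the 2 libraries had a Spearman rho of 0.81. On the log2 scale, with 1 count added, their Pearson r was 0.661. The median log2 fold was 0.02. The excess of higher over lower genes turned with the count minimum and the scaling: a minimum of 10 counts gave 5404 higher and 5624 lower genes, and upper-quartile scaling gave 2908 and 2914.

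Large folds were counted with and without a minimum in the lower library, a choice made after the data were seen. Without one, 706 genes were at least 16-fold higher in LT and 376 were at least 16-fold lower, and 304 and 259 passed 64-fold. Many of these folds are set by the added 1 count, since the lower library held 0 or very few counts. Among genes with at least 10 counts in the lower library, 213 were at least 16-fold higher and 29 were at least 16-fold lower, and 42 and 0 passed 64-fold. This minimum leaves out the genes at or near 0 in either library, including those with the largest drops in LT. The 213 genes together held 4.88% of the LT counts and 0.111% of the CK counts. With the same minimum, the 5 other scalings gave 197 to 224 genes at least 16-fold higher and 21 to 37 at least 16-fold lower.

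The gene numbered c32525.graph_c0, a single sequence of 1392 bases, had the highest fold in LT among genes with at least 100 counts in the higher and 10 in the lower library. It had 30451 counts in LT and 28 in CK, or 1506 and 1.48 TPM, a log2 fold of 9.84 (95% counting interval 9.35 to 10.47). It was followed by c34576.graph_c0, with 6 isoforms and a length of about 1549 bases in LT, which had 18228 counts in LT and 18 in CK, or 804.1 and 0.84 TPM. Its log2 fold was 9.71 (9.12 to 10.53). In the other direction, c26184.graph_c0, of 811 bases, had 42 counts in LT and 2278 in CK, or 3.78 and 217.1 TPM, and a log2 fold of -5.93 (-6.44 to -5.53). The next, c9100.graph_c0, of 1005 bases, had 141 counts in LT and 5772 in CK, or 9.96 and 433.7 TPM, and a log2 fold of -5.55 (-5.81 to -5.32). Each of the 4 differences exceeded its counting error, but none has a replicate check.

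**Figure D2:**
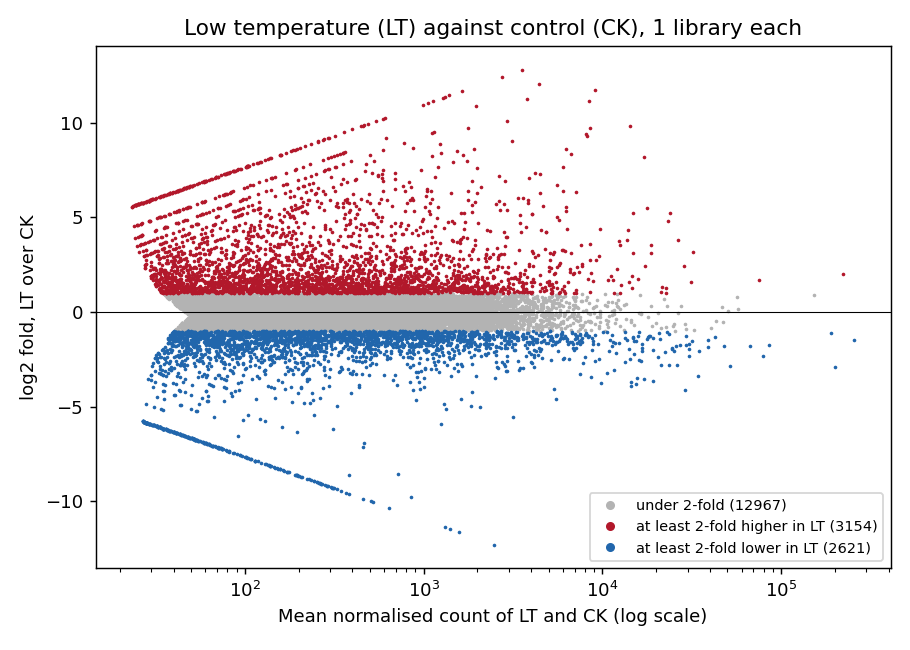
Log2 fold of LT over CK (vertical axis) against the mean normalised count (horizontal axis, log scale), with 1 point per assembled gene of the 18742 compared. The 3154 genes at least 2-fold higher and the 2621 at least 2-fold lower are coloured, and the straight slanting rows of points at the edges are genes with 0 or very few counts in 1 library, whose plotted fold is set by the added 1 count.

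Among the most abundant transcripts, those lower in LT outnumbered those higher in LT. Of the 171 genes with a mean normalised count of 10000 or more, 76 (44.4%) were at least 2-fold lower in LT and 35 (20.5%) were at least 2-fold higher, and the median log2 fold of this class was -0.76. In the class from 3000 to below 10000, 155 of 781 genes were higher and 155 were lower. In the class from 300 to below 1000, which held 5815 genes, 12.7% were higher and 9.22% were lower, with a median log2 fold of 0.04. The median of the most abundant class stayed between -0.85 and -0.67 under the 5 other scalings.

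**Figure D3:**
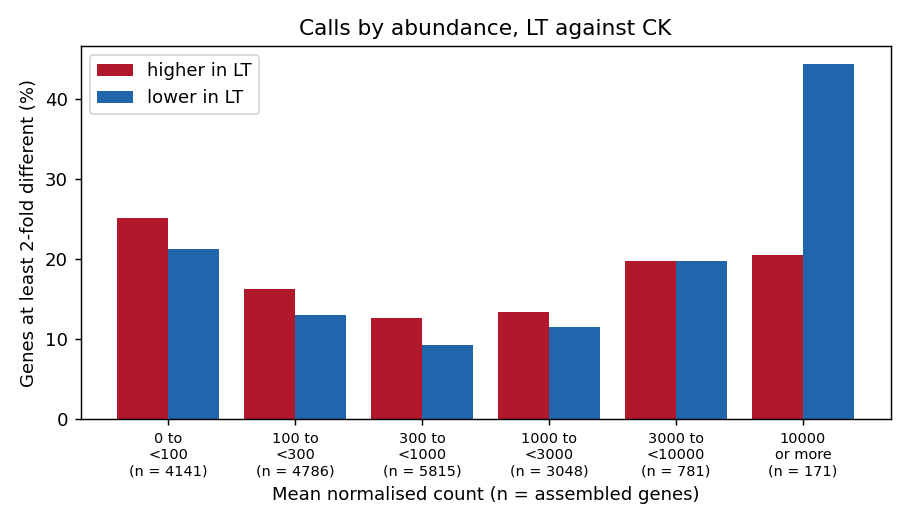
Share of assembled genes at least 2-fold higher or lower in LT than in CK (percent, vertical axis) by class of mean normalised count (horizontal axis, number of genes in brackets). The class of 10000 or more has the highest share of lower genes, 44.4%, against 20.5% higher.

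The share of genes called was also counted by length and by isoform number. Among genes of 500 to below 1000 bases, 20.9% were at least 2-fold higher in LT and 16.5% lower, against 10.2% and 9.09% among the 3894 genes of 2000 bases or more. Among the 7642 single-isoform genes, 21.2% were higher and 17.1% lower, against 8.05% and 8.47% of the 2398 genes with 10 or more isoforms. Length, isoform number and abundance are related to each other, and their contributions were not separated.

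Some genes were listed at 0 in 1 of the libraries. There were 193 genes with at least 50 counts in LT and 0 in CK, with a median of 108 counts in LT and a highest value of 7647. There were 302 genes with at least 50 counts in CK and 0 in LT, with a median of 95.5 counts in CK and a highest value of 4601. Their folds depend on the added 1 count, and none is given for a single gene of these sets. Without all genes at 0 in either library, an alternative added after the data were seen, 2961 genes were at least 2-fold higher in LT and 2319 were lower.

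How many of these differences would recur in other plants depends on the spread between plants and on library effects, and neither was measured. In simulated libraries with counting noise alone, 6 of 17729 unchanged genes (0.0338%) passed the 2-fold limit. With an assumed biological coefficient of variation of 0.2 between libraries it was 450 of 17879 (2.52%), and with 0.4 it was 4556 of 18021 (25.3%). The assumed value applies to a whole library, here a mixture of 4 parallel samples, and not to single plants, whose spread the mixing averages. It was drawn gene by gene, so the simulation holds no library effect common to many genes.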

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

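The abundance-weighted length of a gene, whose difference between LT and CK is not described above, differed by at least 1.2-fold in 386 of 9590 multi-isoform genes with at least 50 counts in both libraries, a limit chosen after the values were seen. It was longer in LT for 196 of them and longer in CK for 190. The share was 7.42% for genes with 50 to below 100 counts in the lower library and 3.59% for the 362 genes with 3000 or more. Of the 386 genes, 97 were also at least 2-fold higher or lower in LT. Whether length differences and calls go together cannot be decided from this, because calls among all 9590 genes were not counted. Calls were counted only in a wider set, the multi-isoform genes with at least 50 counts in the higher library, which also holds genes below 50 in the other. With 2 isoforms 18.7% were higher and 14.6% lower, with 3 to below 10 isoforms 13.1% and 11.6%, and with 10 or more 8.05% and 8.47%.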

How the results depend on the processing

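With 1 library per group no library could be left out. The planned results on HL against CK, LT against HL, their overlap and their correlation, and on pathway lists, could not be computed under any setting. Of 36 alternative counts of genes higher or lower in LT, 24 stayed within 1.5 times the reported 3154 and 2621. Among these were the 5 other scalings, which gave 2908 to 3432 higher and 2334 to 2914 lower genes; higher genes made up 49.9% to 59.5% of the calls, so that with the upper quartile lower genes (2914) slightly outnumbered higher ones (2908). Other scalings moved the median log2 fold by at most 0.10. When the whole counting interval had to lie at or beyond 2-fold, 2434 genes were higher and 1912 lower, also within 1.5 times the reported numbers. The other calls were not resolved as 2-fold against counting error. The counts outside that range followed from testing more or fewer genes or from another limit. A count minimum of 1 gave 14132 higher and 23767 lower, of 10 gave 5404 and 5624, and of 200 gave 2024 and 1555. A fold limit of 1.5 gave 4881 and 4388, and of 4 gave 1539 and 908. Of the 3 alternatives added after the data were seen, genes with 1 isoform gave 1622 and 1304, at least 10 counts in the lower library gave 2530 and 2230, and leaving out genes at 0 in either library gave 2961 and 2319. The excess of lower genes at minimums of 1 and 10 reverses the split. Detection at 1 count instead of 10 gave 49268 genes in LT, 63470 in HL and 56613 in CK, and at 50 counts 17512 in LT, 16877 in HL and 16665 in CK. None of 32 alternative values for the 4 named genes left its counting interval or changed sign. Because these genes were picked for the largest folds, a change of sign could hardly occur, and this says little about other genes. Thinned to the CK total, LT had 24917 genes with at least 10 counts, below the 25342 of CK, whereas at its own depth it had 25461.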

Other observations

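The tests in this part were chosen after the values they explain had been seen, except those that shifted gene numbers and thinned by effective length, whose outcomes were predicted first. Genes at 0 were counted by length class. Among the 31746 shortest assembled genes, of 200 to below 300 bases, 60.6% were at 0 in LT and 46.5% in CK. Among the 8580 genes of 1000 to below 2000 bases, 2.67% were at 0 in LT and 0.816% in CK. On its own assembly, HL had 0.0685% of 8753 genes of that length at 0. Over all lengths, 25511 genes were at 0 in LT and 18166 in CK, and 7639 were in both of these sets.

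The TPM values of HL and CK correlated across the 68916 gene numbers they share (Pearson r of 0.568 on log2(TPM + 1), across genes), which would invite a join by number. That a number names the same gene in both files is argued against by the lengths, which were equal for 0.446% of single-isoform genes against 100% between LT and CK. Lengths alone do not settle it, because LT and CK share 1 assembly and a second assembly could give the same gene another length. When the HL values were moved by 1 to 20 places along the numbering, the mean r was 0.569 over 40 shifts (0.566 to 0.573), so the correlation is consistent with the place of a number in the assembler's order carrying abundance. The same shift lowered the r of LT and CK, whose numbers do name the same genes, from 0.862 to 0.595. That the r of HL and CK did not fall argues against shared genes under these numbers. A table of HL folds made by joining on these numbers would therefore compare unrelated sequences.

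The 302 genes with at least 50 counts in CK and 0 in LT were set beside genes with low counts in LT. Among genes with 50 to 200 counts in CK, 231 were at 0 in LT, 5 at 1 and 39 at 1 to 5. This argues against chance loss along a falling scale. In the reverse direction, among genes with 50 to 200 counts in LT, 135 were at 0 in CK, 52 at 1 and 175 at 1 to 5. More genes were thus at 0 than at 1 in both directions, and the excess was larger for the genes at 0 in LT. Whether reads shared with near-identical sequences play a part could not be decided from fractional counts. A fractional CK count was held by 9.60% of the 302 genes (exact 95% interval 6.53 to 13.5%), against 33.5% expected from other genes of the same isoform class. Those other genes were not matched on abundance, and the 302 were picked for a count of 0 in LT. RNA of another organism or plant genotype in the CK library may be the source. Without sequences this cannot be told apart from genes silent at low temperature, which also stays open. Of the 302 genes, 139 have 1000 bases or more, which does not bear on the source. The share is larger among the 18742 genes compared, of which 7772 had 1000 to below 2000 bases and 3894 had 2000 or more.

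Fewer genes had at least 1 count in LT (49268) than in CK (56613). Depth is argued against, because the total count of LT, 18836786, was higher than that of CK, 17223244. The shorter effective lengths in LT, as longer reads would give, are argued against as the whole cause: CK thinned gene by gene by the ratio of effective lengths kept 55909. A few abundant genes taking the depth are argued against as well, since the top 10 genes took 6.91% of LT and 9.27% of CK. A difference in library preparation, RNA of another organism or plant genotype in the CK library, and an effect of temperature possibly remain. None of them could be tested with 1 library each and without sequences.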
